A study of Homo sapiens with 6 samples.

How the data were processed

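Reads from ribosomal RNA were counted along the 18S rRNA of the small ribosomal subunit and the 28S rRNA of the large subunit in 6 human RNA-seq libraries. Per the labels' protocols, mature sperm were selected by centrifugation through 50% Percoll, a silica medium that separates cells by density. Their RNA was extracted, cleared of genomic DNA and made into libraries with the Illumina mRNA-Seq kit, and the testis RNA was bought. Sequencing was paired-end with 36-nt reads on a Genome Analyzer, per the labels. The labels name the RNA of 3 sperm libraries as total RNA, and that of 1 further sperm library and of both testis libraries as poly(A) RNA. The poly(A) sperm library came from the same donor as the total RNA library called replicate 1. The protocol text speaks of total testis RNA, and the labels do not state how much poly(A) selection the testis RNA went through. The characteristics give 2 lanes for each sperm library and 1 lane for each testis library, whereas the protocol text gives 2 lanes for each sample.

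The deposited data were 12 tracks, 1 per library and rRNA, each with a single whole number per nucleotide from position 1. They are used as deposited read counts per position, with no normalization, per the file headers and the values. Novoalign is named in the submitters' processing notes. Its version and options, the rRNA reference sequence and the handling of reads with several alignments or of duplicates are not given in the sources used here. The values cannot be coverage by 36-nt reads. If they were, between 47.1% and 51.9% of positions in each track would need a negative number of read starts. They are therefore treated as counts of reads by one alignment position, and which end of the read that position marks is not given in the sources used here. Positions are those of the deposited tracks. They were cut to the 1837 positions of 18S and 5038 positions of 28S that all libraries hold, which left out at most 18 reads of a track. Tracks of counts by one alignment position can stop short of the end of a molecule, and no rRNA sequence was used here to check this. The ends named below are those of the positions used.

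Each subunit was divided into consecutive windows of 50 nt, 37 on 18S and 101 on 28S, of which the last held 37 nt and 38 nt. The relative count of a window is its mean count per position divided by the library's mean over the same subunit, so that 1 is the subunit's mean and depth cancels. The comparison of sperm total RNA with testis used edgeR's quasi-likelihood test on the summed counts of each window, with the subunit's total count in each library as the offset and Benjamini-Hochberg adjustment over the 138 windows of both subunits. A window was called at an adjusted p under 0.05. The design fixed before the data were examined had assumed coverage and planned limma on log2 relative values. Because the tracks hold counts, edgeR became the main test and limma with the planned pseudocount of 0.02 an alternative. The sperm poly(A) library was kept out of that test. The edgeR fit was tested on simulated data in 20 sets of the 138 windows of this comparison, with 30 windows changed in each. It recovered 20.25% of the windows changed 2-fold and 75% of those changed 4-fold, called 0.88% of unchanged windows, and 7.6% of its calls were false. The common dispersion was 0.146, a coefficient of biological variation of 38.3%. The simulated windows were independent and all had this dispersion. Neighbouring windows that move together and libraries of unequal spread were not simulated, so these rates need not hold for the calls below.

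Measures were taken per library and subunit. They were the coefficient of variation of the counts over positions, the percentage of positions below 10% of the library's mean, the percentage of reads in the 3′-most 50% of the molecule, and the ratio of mean counts per position on 28S and 18S. Group means were compared by an exact two-sided permutation test over all splits of the 5 libraries (scipy). The smallest p this test can give with 3 libraries against 2 is 0.2, so it cannot reach 0.05. Runs of at least 10 poorly covered positions were listed as gaps. Profiles were compared by Pearson and Spearman correlation across windows of log2(relative count + 0.02). Windows are not independent replicates, so the one-sided p came from all circular shifts of one profile by whole windows, with Benjamini-Hochberg adjustment over the 15 pairs of libraries. Shares given for single libraries carry 95% Wilson intervals, which cover counting error only, since these reads have no molecular identifiers.

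Before the data were examined, a rule fixed which windows would be named. Per subunit it named the 5 highest and the 5 lowest log2 differences among called windows. All 3 sperm values of these windows had to lie on one side of both testis values. Also named were the end windows, the most and least covered 10% segments, and the 5 longest gaps shared by the 3 sperm total RNA libraries. The rule was written for limma differences and calls. It was applied to those of edgeR after the change of test, so the list is not strictly the one fixed in advance. Other window widths, pseudocounts, scalings, filters, tests and sets of replicates were run as alternatives, and their effect is given after the results. The sperm total RNA libraries held between 42867852 and 56513132 reads on the 2 rRNAs, the sperm poly(A) library 1100464 and the testis libraries 315705 and 874275. No pair of libraries was identical, and the lowest chi-square of any pair, which grows with depth, was 75.4 per degree of freedom over the 138 windows, for the testis pair. Tissue, source of the RNA (extracted from sperm or bought), number of lanes and the labelled kind of RNA differ together between the main groups. No fit can separate them. Depth differs with them and was equalised in an alternative by thinning every library to the shallowest. The planned comparison with GC content and the planned windows around conserved sites were not run, because no 18S or 28S sequence of the deposited lengths was used here. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.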

Results

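The distribution of rRNA reads along the mature 18S and 28S molecules was examined in human spermatozoa and testis, with the question whether the rRNA of mature sperm is present as whole molecules or in pieces. Counts by alignment position do not measure the length of molecules. The results below therefore describe where reads lie and do not answer that question. The 18S and 28S rRNAs are the RNA cores of the small and large ribosomal subunits. Total RNA of sperm from 3 donors gave 3 libraries, poly(A) RNA of sperm from the donor of replicate 1 gave 1 library, and 2 purchased testis RNAs, labelled poly(A), gave 2 libraries. Whether each purchased RNA came from a single person is not given in the labels, so the spread between the testis libraries may be technical.

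The libraries differed widely in depth. The sperm total RNA libraries held 42867852, 56513132 and 44579984 rRNA reads for replicates 1, 2 and 3. The sperm poly(A) library held 1100464, and testis replicates 1 and 2 held 315705 and 874275. Mean depth ranged from 45.0 reads per position on 28S in testis replicate 1 to 8269 on 28S in sperm total replicate 2. At most 5.08% of the positions of any track had no read. All comparisons below are of the shape of the profile within a subunit or of the ratio between subunits, not of the amount of rRNA.

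Sperm rRNA reads were less evenly spread than testis reads on both molecules. On 18S, the coefficient of variation of counts over positions was 2.17 ± 0.22 in sperm total RNA (SD, n = 3) against 1.36 ± 0.0045 in testis (SD, n = 2). On 28S it was 1.99 ± 0.11 against 1.58 ± 0.015. Positions below 10% of the library's mean made up 23.3% ± 6.50 of 18S in sperm and 11.2% ± 0.423 in testis. On 28S they made up 31.7% ± 6.31 and 21.5% ± 1.07. All 3 sperm values lay above both testis values in each of these 4 comparisons, and the exact permutation test gave p = 0.2 each time, the smallest value that 3 libraries against 2 allow. The sperm poly(A) library lay between the groups in all 4, with coefficients of variation of 1.79 on 18S and 1.77 on 28S and with 16.4% and 23.5% of positions poorly covered. These positions are called poorly covered below, although the values are counts by one alignment position. Running sums over 36 nt, the closest to coverage by reads and chosen after the data were seen, gave coefficients of 0.959 ± 0.11 against 0.446 ± 0.0014 on 18S and 1.12 ± 0.10 against 0.785 ± 0.019 on 28S. Their differences were 0.514 and 0.332 in place of 0.806 and 0.409. By these sums 11.4% ± 9.33 of 18S and 24.0% ± 7.15 of 28S were poorly covered in sperm, and 0.277% ± 0.392 and 11.8% ± 1.30 in testis (exact permutation p = 0.2 for all 4). Part of the unevenness lay in few positions. With counts capped at the 99th percentile the coefficients fell to 1.62 ± 0.097 against 1.24 ± 0.019 on 18S and 1.70 ± 0.11 against 1.45 ± 0.0072 on 28S, so the differences went to 0.387 and 0.256, without overlap (exact permutation p = 0.2 for both). Defined against the median in place of the mean, the poorly covered share of 18S was 11.0% ± 2.59 in sperm and 6.40% ± 0.0385 in testis, a difference of 4.60 in place of 12.1 percentage points, without overlap (exact permutation p = 0.2). The share of 28S was 17.4% ± 4.60 in sperm and 13.6% ± 0.702 in testis, and the groups overlapped (exact permutation p = 0.6).

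**Figure D1:**
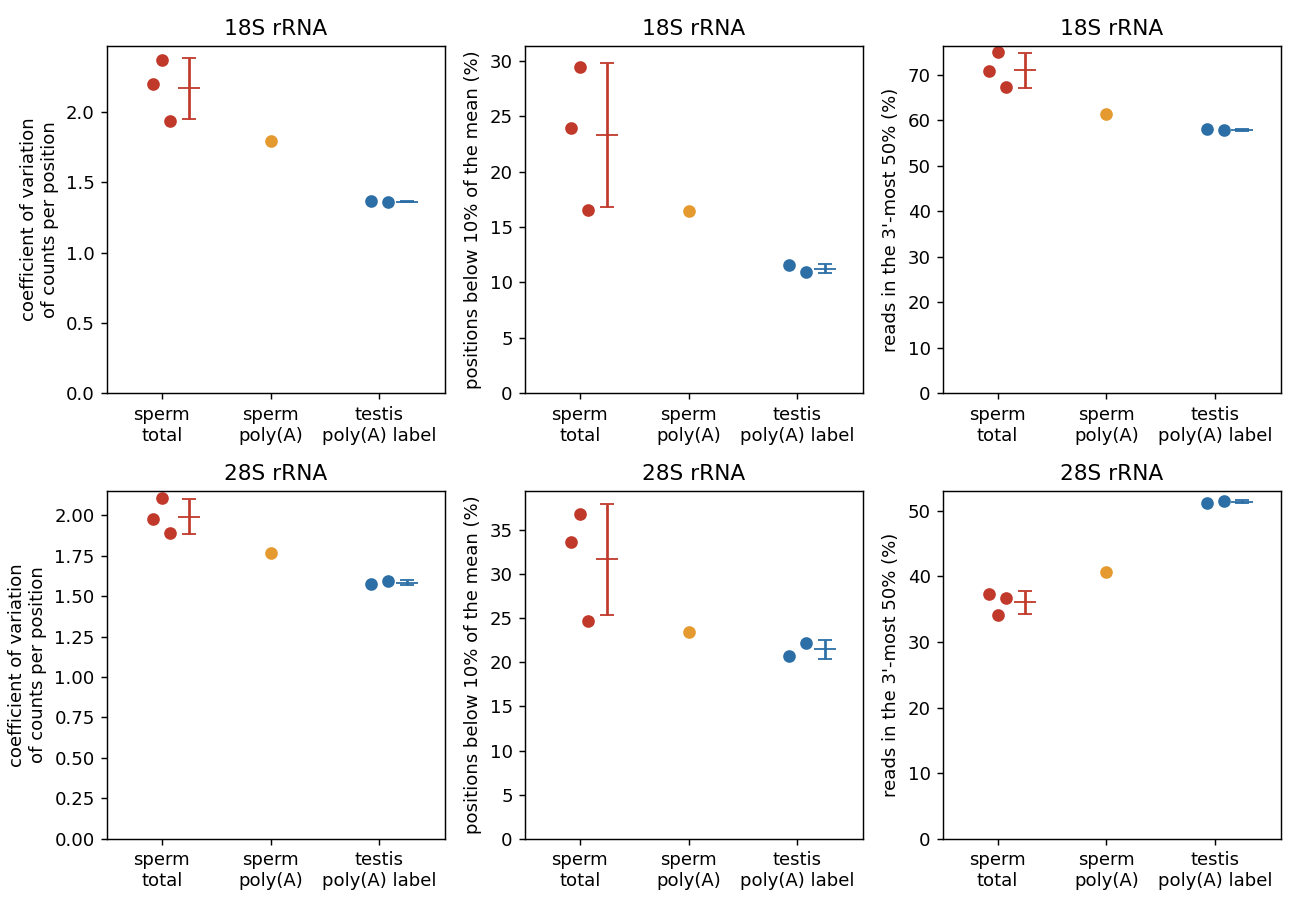
Coefficient of variation of counts per position, percentage of positions below 10% of the mean and percentage of reads in the 3′-most 50% of the molecule, for 18S (top row) and 28S (bottom row). Points are single libraries and bars show the mean ± SD of sperm total RNA (n = 3) and testis (n = 2). On 28S the sperm libraries placed 36.1% of reads in the 3′-most 50%, against 51.4% in testis, and on 18S the order was the opposite, 71.0% against 57.9%.

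The 2 subunits were skewed in opposite directions in sperm. The 3′-most 50% of 18S, from position 919, held 71.0% ± 3.86 of its reads in sperm total RNA and 57.9% ± 0.190 in testis. The 3′-most 50% of 28S, from position 2520, held 36.1% ± 1.72 in sperm and 51.4% ± 0.194 in testis. Groups did not overlap on either molecule, and the exact permutation p was 0.2 for both, again the smallest possible. In the sperm poly(A) library the shares were 61.5% on 18S (95% Wilson interval 61.3 to 61.7) and 40.7% on 28S (40.6 to 40.8), on the sperm side of testis in both. In the last of 3 equal parts of 28S the shares were 28.9% ± 1.09 in sperm total RNA and 37.3% ± 0.235 in testis. The difference was -8.44 in place of -15.4 percentage points. On 18S they were 52.6% ± 1.27 and 40.2% ± 0.490, a difference of 12.4 in place of 13.1 (exact permutation p = 0.2 for both).

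The most used part of each molecule, and the least used part of 28S, were the same in sperm total RNA and testis, whereas the least used part of 18S was not. Among 10% segments, positions 1286 to 1469 held the most 18S reads in both groups, 25.9% ± 1.02 in sperm total RNA and 17.9% ± 0.450 in testis. The lowest mean share of 18S in sperm total RNA was at positions 184 to 367, with 3.90% ± 0.654 against 7.27% ± 0.518 in testis. This rests on replicate 3, since in replicates 1 and 2 positions 1 to 183 held fewer reads, 3.85% (95% Wilson interval 3.84 to 3.86) and 1.91% (1.90 to 1.92), against 8.20% (8.19 to 8.22) in replicate 3 and 11.6% ± 0.114 in testis. The lowest share in testis was at positions 735 to 918, with 5.49% ± 0.257 against 6.50% ± 0.378 in sperm. On 28S, positions 1512 to 2015 held the most, 24.3% ± 1.32 in sperm total RNA and 17.1% ± 0.507 in testis. In the sperm poly(A) library they held 16.2% (95% Wilson interval 16.1 to 16.3), and positions 1 to 503 held as much, 16.3% (16.2 to 16.4). Positions 3023 to 3526 of 28S held the fewest in every group, 0.555% ± 0.426 in sperm, 0.996% ± 0.210 in testis and 1.00% in the sperm poly(A) library (95% Wilson interval 0.981 to 1.02). Without sperm replicate 3 the sperm value was 0.310% ± 0.0543, and the overlap of sperm total RNA with testis ended. The first 28S segment, positions 1 to 503, held 14.3% ± 2.48 in sperm and 7.82% ± 0.439 in testis. Positions 2520 to 3022 held 6.71% ± 0.708 and 13.4% ± 0.154.

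A gap is a run of at least 10 poorly covered positions. Because the counts are by alignment position, reads placed beside a run shorter than a read can still span it. Gaps are therefore stretches with few counts and not sequence shown to be missing. On 28S, the 3 sperm total RNA libraries shared 21 gaps, which made up 631 nt or 12.5% of the positions used. The testis libraries shared 16, over 386 nt or 7.66%. The shared extent in sperm is nearly that of replicate 3, with 651 nt of gaps, against 1148 and 1364 nt in replicates 1 and 2. The longest ran from position 3336 to 3446, with a relative count of 0.0112 ± 0.00632 in sperm and 0.0268 ± 0.00682 in testis. The next, positions 531 to 616, had 0.00481 ± 0.00354 in sperm and 0.0103 ± 0.00595 in testis. Positions 3457 to 3509 and 3048 to 3096 had 0.0130 ± 0.00728 and 0.0150 ± 0.0135 in sperm, against 0.0392 ± 0.00275 and 0.0184 ± 0.00417 in testis. At 3048 to 3096 sperm replicate 3 was at 0.0304, against 0.00969 and 0.00503 in replicates 1 and 2, so the nearness to testis rests on it. Replicate 3 had the highest sperm value in every gap named here, on both subunits. The gap at positions 2149 to 2197 differed more, with 0.00910 ± 0.00539 in sperm and 0.112 ± 0.0648 in testis. On 18S, 4 gaps were shared by the sperm libraries and covered 72 nt or 3.92%, and testis had none in common. Here too replicate 3 set the extent, with 72 nt, against 144 and 282 nt in replicates 1 and 2. They lay at positions 1809 to 1837, 736 to 757, 1 to 11 and 227 to 236. Those at 1809 to 1837 and 1 to 11 reach the ends of the positions used, and all 4 are shorter than a read. Their relative counts in sperm were 0.00436 ± 0.00265, 0.0148 ± 0.0103, 0.00906 ± 0.00475 and 0.0205 ± 0.0111. In testis they were 0.0740 ± 0.0322, 0.142 ± 0.00283, 0.0310 ± 0.00401 and 0.158 ± 0.0544. Of the 28S positions poorly covered in all 3 sperm total RNA libraries, 60.8% were so in both testis libraries, where 17.4% of all 28S positions were. On 18S the share was 39.6%, against 7.89% of all 18S positions.

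**Figure D2:**
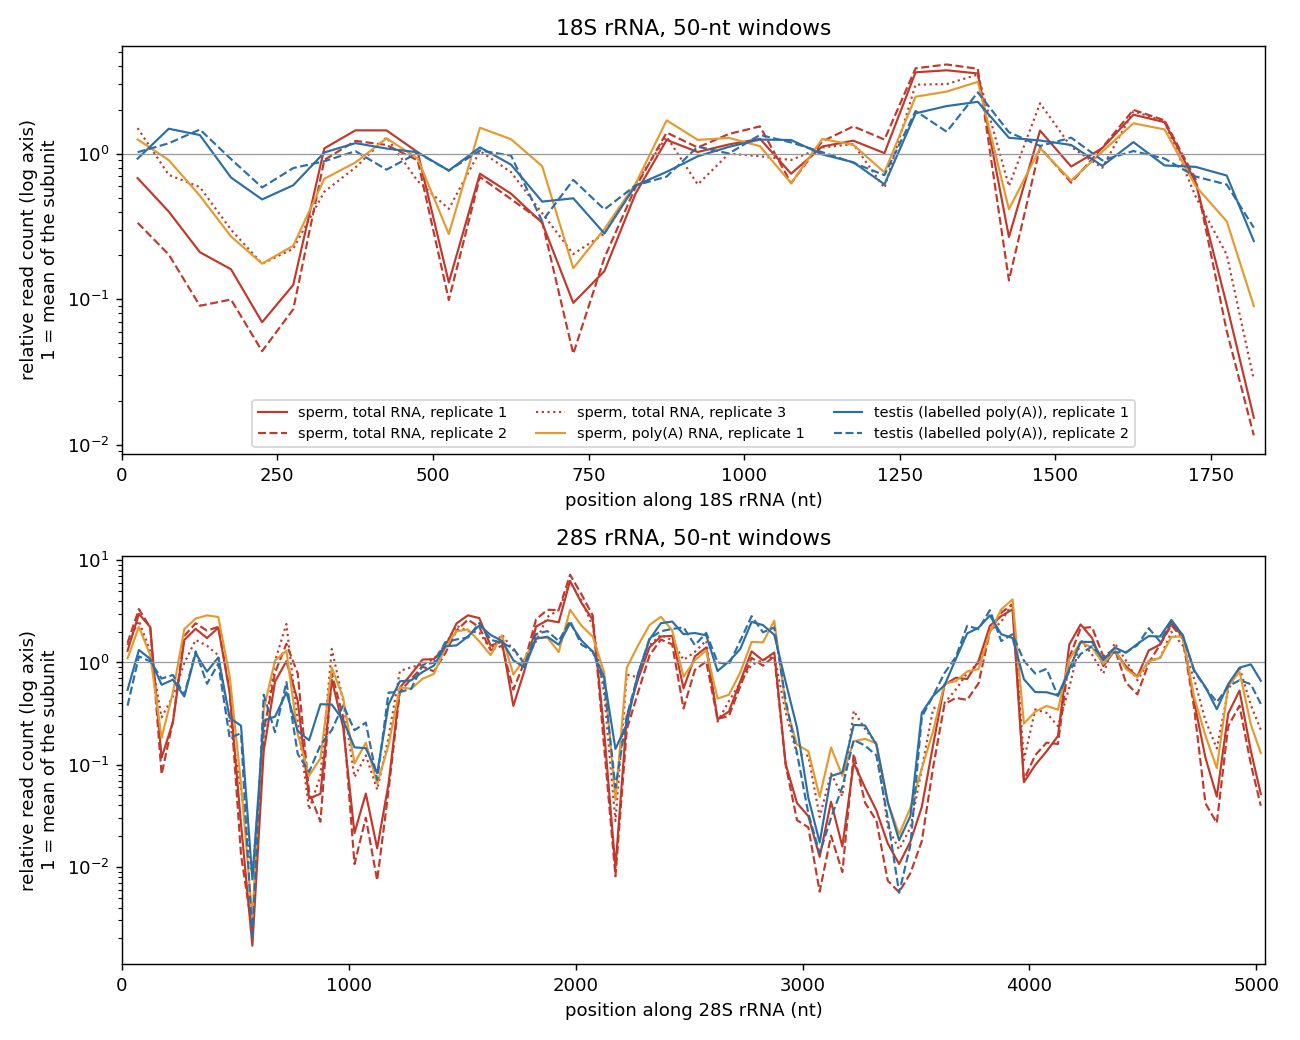
Relative read count in consecutive 50-nt windows (vertical log axis, 1 is the mean of the subunit) along 18S and 28S (horizontal axis, nt) in the 6 libraries, 1 line each. The sperm total RNA libraries fall to relative counts of 0.0116 to 0.0280 in the last 18S window, where sperm poly(A) RNA is at 0.0899 and testis at 0.251 and 0.310, and all libraries drop between positions 2951 and 3500 of 28S.

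The profile of each molecule differed locally between sperm total RNA and testis. By edgeR's quasi-likelihood test, 17 of 37 windows of 18S were called, 6 higher and 11 lower in sperm, and 50 of 101 windows of 28S, 20 higher and 30 lower. In all 67 called windows the 3 sperm values lay on one side of both testis values. Over all windows this held for 25 on 18S (67.6%) and 74 on 28S (73.3%), where chance gives 20%. Called differences reached at least 1 log2 unit in 11 windows of 18S and 34 of 28S. The split by direction depends on single libraries. On 28S, 17 windows were higher and 15 lower without sperm replicate 1, 20 and 19 without replicate 2, and 25 and 49 without replicate 3. On 18S the numbers were 6 and 7, 7 and 10, and 9 and 16. The split also depends on the scaling, since a relative count is a share of the subunit. With TMM factors, a scaling chosen after the data were seen, 8 of 15 called 18S windows and 24 of 34 called 28S windows were higher in sperm. With an equal median window the split was 8 of 17 and 21 of 44. TMM factors kept 13 of the 17 and 30 of the 50 calls and turned the sign of 2 called 28S windows, both lower in sperm in the main fit. Leaving out testis replicate 1 left 9 and 28 calls, testis replicate 2 left 9 and 19, and sperm replicate 1 left 13 and 32 on 18S and 28S. Leaving out sperm replicate 3 raised the calls to 25 and 74. Windows of 100 nt gave 6 of 18 and 17 of 50.

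On 18S, reads in sperm were concentrated around positions 1251 to 1400 and 1601 to 1700 and depleted near both ends. The 3 touching windows from 1251 to 1400 held 29.2% ± 3.17 of 18S reads in sperm total RNA and 16.8% ± 0.519 in testis. Part of this lay in a single position, 1378, in the window from 1351 to 1400. It held 2.52% to 3.53% of 18S reads in the sperm total RNA libraries and 0.632% and 0.795% in testis (intervals are given below). The call of that window ended with RLE factors. The largest fold of the 3 windows was at positions 1301 to 1350, 2.04-fold higher in sperm (log2 difference 1.03 ± 0.18 SE, edgeR adjusted p = 5.52e-05), with relative counts of 3.62 ± 0.560 and 1.77 ± 0.502. Positions 1251 to 1300 were 1.81-fold higher (0.85 ± 0.16, edgeR adjusted p = 8.96e-05). Positions 1651 to 1700, 1601 to 1650 and 851 to 900 were 1.90-, 1.73- and 1.82-fold higher, with relative counts in sperm of 1.67 ± 0.0236, 1.94 ± 0.0762 and 1.32 ± 0.0771. The calls at 1601 to 1650 and 851 to 900 ended without testis replicate 2 (edgeR adjusted p = 0.0874 and 0.104), and the latter also without testis replicate 1 (0.0640).

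The most depleted 18S window was the 3′ end of the positions used, 1801 to 1837. Its relative count was 0.0183 ± 0.00860 in sperm and 0.281 ± 0.0420 in testis, 15.3-fold lower (log2 difference -3.94 ± 0.97 SE, edgeR adjusted p = 0.00210). Its neighbour, positions 1751 to 1800, was 5.60-fold lower (-2.48 ± 0.65, edgeR adjusted p = 0.00321). The 5 touching windows from 51 to 300 held 3.17% ± 2.07 of 18S reads in sperm and 13.0% ± 0.659 in testis. In each of them replicate 3 was the highest of the sperm total RNA libraries, so it raises the sperm share. Of these windows 3 stayed called with TMM factors, and positions 201 to 250 and 251 to 300 were 5.56- and 4.86-fold lower. Positions 701 to 750 were 5.08-fold lower, with 0.114 ± 0.0828 in sperm and 0.578 ± 0.118 in testis. Without testis replicate 2 the adjusted p of positions 201 to 250, 251 to 300 and 701 to 750 rose to 0.104, 0.104 and 0.132 by edgeR. The calls at 201 to 250 and 701 to 750 also ended without testis replicate 1 (0.0672 and 0.0614) or sperm replicate 1 (0.0534 and 0.0503), and that at 1751 to 1800 without testis replicate 1 (0.0863). Sizes also moved. Without sperm replicate 3 the log2 differences of positions 201 to 250, 701 to 750 and 1751 to 1800 were -3.24, -3.08 and -3.12, against -2.48, -2.35 and -2.48. The planned limma fit gave -2.99 at the 3′ end, and -1.68 with a pseudocount of 0.1, so the 15.3-fold value depends on how near-empty windows are handled. The first window, positions 1 to 50, was not called, with 0.838 ± 0.598 in sperm and 0.975 ± 0.0700 in testis (log2 difference -0.22 ± 0.39, edgeR adjusted p = 0.673). Its difference turned with the scaling, to 0.13 with an equal median window and 0.088 with TMM factors, and without sperm replicate 3 it was called (-0.94, edgeR adjusted p = 0.00133).

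**Figure D3:**
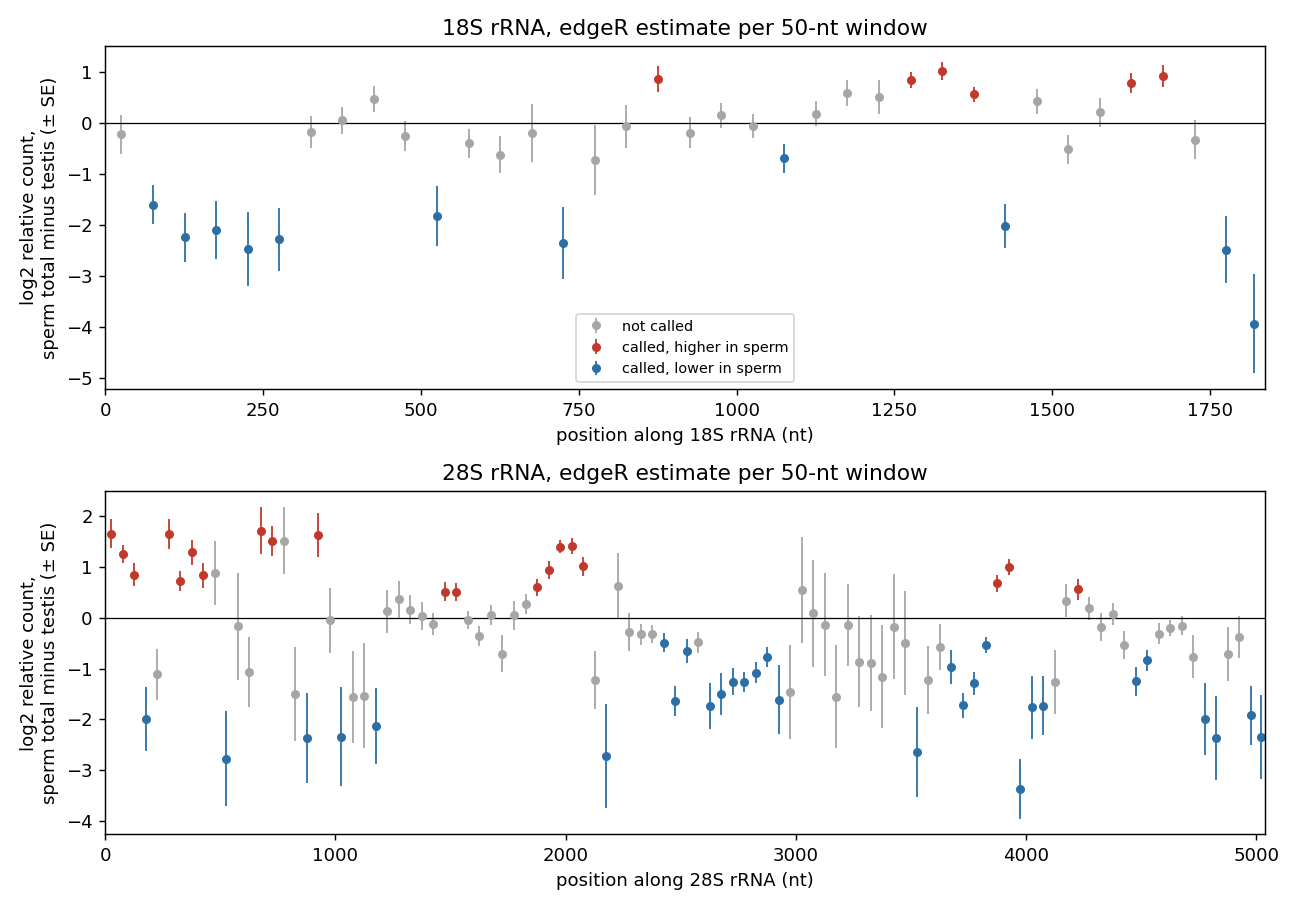
Log2 difference in relative count between sperm total RNA and testis (vertical axis, points, with standard errors as bars) in 50-nt windows along 18S and 28S (horizontal axis, nt). Coloured points are called by edgeR, 6 higher and 11 lower in sperm on 18S and 20 higher and 30 lower on 28S, and grey points are not called.

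On 28S, called windows higher in sperm lay mostly in the 5′-most 50% and lower ones mostly in the 3′-most 50%, with exceptions in both. By window centre, 17 were higher and 8 lower in the 5′-most 50%, and 3 were higher and 22 lower in the 3′-most 50%. With TMM factors the numbers were 20, 2, 4 and 8. Positions 1 to 150 held 6.26% ± 0.886 of 28S reads in sperm and 2.73% ± 0.281 in testis, and positions 251 to 450 held 7.12% ± 1.68 and 3.47% ± 0.191. The 5 touching windows from 1851 to 2100 held 19.1% ± 1.84 in sperm, 8.74% ± 0.251 in testis and 10.3% in the sperm poly(A) library (95% Wilson interval 10.2 to 10.4). The 5 named windows that were higher in sperm all lay in the first 950 nt. Positions 651 to 700 were 3.29-fold higher (log2 difference 1.72 ± 0.47 SE, edgeR adjusted p = 0.00393), with 0.827 ± 0.193 in sperm and 0.252 ± 0.0622 in testis. The 5′ end, positions 1 to 50, was 3.16-fold higher (1.66 ± 0.29, edgeR adjusted p = 5.52e-05). Positions 251 to 300, 901 to 950 and 701 to 750 were 3.14-, 3.09- and 2.85-fold higher. Without testis replicate 2 the calls at 651 to 700 and 901 to 950 ended, each at an edgeR adjusted p of 0.0874.

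In the 3′ part, positions 2601 to 2950 held 4.70% ± 0.249 of 28S reads in sperm and 10.7% ± 0.349 in testis, over 7 touching called windows, of which 3 stayed called with TMM factors. Positions 3651 to 3850 held 4.17% ± 0.622 and 8.37% ± 0.501, and 2 of their 4 windows stayed called. The largest called difference on 28S was at positions 3951 to 4000, with 0.0834 ± 0.0241 in sperm and 0.863 ± 0.251 in testis, 10.4-fold lower (log2 difference -3.37 ± 0.59 SE, edgeR adjusted p = 5.52e-05), next to positions 3851 to 3950, which held 6.37% ± 0.321 of reads in sperm and 3.54% ± 0.0804 in testis. Not all strong depletion was in the 3′ part. Positions 501 to 550, 2151 to 2200, 3501 to 3550 and 851 to 900, of which only 3501 to 3550 lies beyond position 2520, were 6.84-, 6.57-, 6.26- and 5.19-fold lower in sperm. These 4 windows had relative counts of 0.0324 ± 0.0232, 0.0154 ± 0.0111, 0.0492 ± 0.0377 and 0.0526 ± 0.0252 in sperm. The 3′ end, positions 5001 to 5038, was 5.09-fold lower, with 0.104 ± 0.101 in sperm and 0.528 ± 0.191 in testis (edgeR adjusted p = 0.0203). The calls at these 4 windows and at the 3′ end ended without either testis library, and also without sperm replicate 1. Over these settings the edgeR adjusted p reached 0.143, 0.347, 0.136 and 0.450 at the 4 windows and 0.289 at the 3′ end. Without sperm replicate 2 the calls at 501 to 550, 2151 to 2200, 851 to 900 and the 3′ end ended too (edgeR adjusted p = 0.0536, 0.0845, 0.0774 and 0.0506), and that at 3501 to 3550 held (0.0476). The sizes were not stable either. Without sperm replicate 3 the log2 differences at 501 to 550, 2151 to 2200, 3501 to 3550 and the 3′ end were -3.50, -3.49, -3.45 and -3.53, against -2.77, -2.72, -2.65 and -2.35. Without testis replicate 1 those at 2151 to 2200 and 851 to 900 were -1.96 and -1.56, against -2.72 and -2.38. With TMM factors the calls at 2151 to 2200, 851 to 900 and the 3′ end also ended (edgeR adjusted p = 0.0536, 0.0565 and 0.0703).

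Profiles were most alike within a tissue, and the sperm poly(A) library grouped with the other sperm libraries. On 18S, the mean Pearson r across windows was 0.925 over the 3 pairs of sperm total RNA libraries, 0.927 for the testis pair and 0.686 over the 6 sperm total RNA with testis pairs. The sperm poly(A) library had a mean r of 0.925 with sperm total RNA and 0.677 with testis. On 28S the corresponding means were 0.965, 0.977, 0.837, 0.954 and 0.850. Spearman's rho gave 0.890, 0.936, 0.575, 0.869 and 0.533 on 18S and 0.962, 0.973, 0.799, 0.943 and 0.798 on 28S. Every one of the 15 pairs exceeded all circular shifts of its profile, with an adjusted p of 0.027 on 18S and 0.0099 on 28S, the smallest that these permutations can give. These values were the same for pairs within and between tissues, so they show only that profiles line up by position. The higher r within a tissue was not tested.

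Within the donor of replicate 1, poly(A) and total RNA of sperm differed by an amount within the range between donors of sperm total RNA only when replicate 3 was included. The log2 differences of the 138 windows had an SD of 0.70 between these libraries, and 77.5% lay within 1 log2 unit. Pairs of sperm total RNA libraries had SDs of 0.35 (replicates 2 and 1), 0.69 (3 and 1) and 0.86 (3 and 2), the testis pair 0.35, and the sperm poly(A) library against testis replicates 1 and 2 had 0.85 and 0.94. Only the pair of replicates 3 and 2 exceeded the SD of 0.70. For replicates 2 and 1, the pair without replicate 3, 98.6% of windows lay within 1 log2 unit. With 1 library of each kind the comparison of poly(A) with total RNA has no replicate check. The median window was 0.35 log2 units higher in poly(A) RNA.

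The sperm poly(A) library was set beside the called windows, as the only sperm library with the RNA label of testis. The testis RNA was bought and may be total RNA by the protocol text. Tissue therefore cannot be separated here from the source or preparation of the RNA. The rRNA read counts of testis, 315705 and 874275, were nearer that of the sperm poly(A) library (1100464) than those of sperm total RNA (42867852 to 56513132). This goes with the poly(A) label, but the total reads of each library were not used here, so it does not settle the kind of RNA. The poly(A) library also shares its donor with total RNA replicate 1, which entered the calls. In 63 of the 67 called windows (94.0%) the poly(A) library lay beyond both testis libraries on the side of sperm total RNA. An exchangeable library would do so in 33.3%, and simulated further testis libraries, which share the testis controls of the calls, did so in 39.7% on average and in 58.2% at most over 1000 draws. The median difference from testis in the direction of the call was 0.99 log2 units for the poly(A) library and 1.41 for sperm total RNA. Across the 138 windows the log2 differences of the 2 kinds of sperm RNA from testis correlated with r = 0.844 (rho = 0.829), against 0.445 simulated for unchanged profiles that share the testis libraries. The covariance was 0.821, against 0.145 simulated, a difference of 0.677. Without the sperm total RNA library of the same donor, r was 0.851.

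Mean counts per position were similar on the 2 subunits. The ratio of 28S to 18S was 0.949 ± 0.104 in sperm total RNA (SD, n = 3) and 1.05 ± 0.172 in testis (SD, n = 2), a difference within the spread between libraries (exact permutation p = 0.6). It was 1.31 in the sperm poly(A) library. The order of sperm and testis turned without testis replicate 2, which left a testis value of 0.929. Without the outer 100 nt of each subunit the ratio was 0.872 ± 0.0734 in sperm and 1.04 ± 0.169 in testis, and the groups did not overlap (exact permutation p = 0.2, the smallest possible).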

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

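The main edgeR fit replaced the planned limma fit once the tracks were seen to hold counts. The fits with TMM, RLE and DESeq2 size factors, equal depth, capped counts and 36-nt running sums were also chosen after seeing the data. The measures per library kept their direction under the alternatives run, apart from the 28S to 18S ratio, whose difference (sperm minus testis) changed sign with the sperm poly(A) library in place of sperm total RNA (0.263) and ranged from -0.222 to 0.0209 with replicates left out. The cause was not tested. With the sperm poly(A) library the other differences (sperm minus testis) kept their direction but were smaller. The poorly covered share went from 12.1 to 5.20 percentage points on 18S and from 10.2 to 2.00 on 28S. The 3′-most share went from 13.1 to 3.57 on 18S and from -15.4 to -10.7 on 28S. The coefficients of variation went from 0.806 to 0.428 and from 0.409 to 0.184. In 100-nt windows the mean r of sperm pairs on 18S was 0.922 with an adjusted permutation p of 0.0556, the smallest that 18 shifts allow, and 6 windows of 18S and 17 of 28S were called among fewer tested. Leaving out 1 library gave 9 to 25 called windows on 18S and 19 to 74 on 28S, against 17 and 50. The highest counts, 25 and 74, were without sperm replicate 3. A lone testis library was assumed to vary like the sperm libraries. The other fits called 14 to 21 and 34 to 60.

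Scaling moved the median window by 0.30 (18S) and 0.53 (28S) log2 units with TMM factors, 0.13 and 0.42 with RLE factors and 0.36 and 0.30 with an equal median window. The share of called 28S windows lower in sperm was 60% in the main fit, 29.4% with TMM, 48.8% with RLE, 52.3% with an equal median window and 71.4% with limma. Of the 22 named windows, the 21 called ones kept their direction in each alternative. The uncalled 18S window 1 to 50 turned to 0.13 with an equal median window, 0.16 without sperm replicate 2 and 0.088 with TMM, and ranged from -0.94 to 0.16 with a library left out. Named calls were lost in 35 of the 417 values from alternatives, 32 of them with a library left out and 3 with TMM. The sizes of depleted windows with few reads shrank in the planned limma fit, and more so with its pseudocount raised to 0.1: from -3.94 to -2.99 and -1.68 at the 18S 3′ end, from -2.72 to -1.73 and -0.78 at 28S 2151 to 2200, and with 0.1 from -3.37 to -2.38 at 28S 3951 to 4000. The GC comparisons were not run for want of a sequence. No paired analysis was possible because the labels do not tie any testis RNA to a sperm donor. Depth limits the shared gaps, where testis replicate 1 had as few as 15 reads on 18S and 47 on 28S.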

Other observations

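The tests of explanations below, and the choice of steps and single positions, were made after the profiles had been seen. Of the 136 steps between neighbouring windows, taken in log2 units after adding 0.02 to each relative count, 55 were larger in all 3 sperm total RNA libraries than in both testis libraries and 20 were larger in both testis libraries, where chance gives 10% each. Between positions 3901 to 3950 and 3951 to 4000 of 28S, the relative count itself, with nothing added, fell 49.0-, 51.9- and 34.5-fold in sperm total replicates 1, 2 and 3 and 16.4-fold in the sperm poly(A) library. It fell 2.53- and 1.82-fold in testis replicates 1 and 2. Between positions 1351 to 1400 and 1401 to 1450 of 18S, the falls were 13.3-, 28.5- and 5.84-fold in sperm total RNA, 7.50-fold in sperm poly(A) RNA, and 1.77- and 1.88-fold in testis. Between positions 851 to 900 and 901 to 950 of 28S the sperm count rose, with 0.02 added, by 3.28, 4.07 and 3.81 log2 units in total RNA and 2.75 in poly(A) RNA, against -0.01 and 0.44 in testis. In the other direction, between positions 501 to 550 and 551 to 600 of 28S the count fell 31.8- and 104-fold in testis, against 15.4-, 5.38- and 7.28-fold in sperm total RNA and 20.6-fold in sperm poly(A) RNA. The second window held only 17 and 13 reads in testis and 27 in the poly(A) library, so these folds are rough. Steps were read from a fixed grid of 50-nt windows and were not located to the nucleotide.

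The positions with the most reads were also shared within a tissue. Of the top 18 positions of 18S, the top 1%, pairs of sperm total RNA libraries shared 13.7 on average, the testis pair 13, the poly(A) library with sperm total RNA 11.0, and sperm total RNA with testis 5.83, where independent lists would share 0.176. Of the top 50 positions of 28S the numbers were 35.3, 39, 25.3 and 14.2, against 0.496. A single 18S position, 1378, held 3.07% (95% Wilson interval 3.06 to 3.08), 3.53% (3.52 to 3.54) and 2.52% (2.51 to 2.53) of 18S reads in sperm total replicates 1, 2 and 3. It held 2.27% (2.21 to 2.33) in sperm poly(A) RNA and 0.632% (0.582 to 0.687) and 0.795% (0.757 to 0.834) in testis. The next position held 58.9 to 82.6 times fewer reads in the 6 libraries. The mean Pearson r with testis was 0.778 on 18S and 0.859 on 28S for sperm total replicate 3, against 0.690 and 0.842 for replicate 1 and 0.591 and 0.809 for replicate 2. By Spearman's rho replicate 3 was highest on 18S (0.662, against 0.577 and 0.486) but replicate 1 on 28S (0.821, against 0.771 for replicate 2 and 0.804 for replicate 3).

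The differing windows between sperm total RNA and testis were weighed against 3 technical accounts. Unequal depth was not needed for the calls: thinned to the shallowest library, 66 of the 67 called windows were still called. This is a weak test of depth. Thinning could change few calls, since even that library averaged 45.0 reads per position on 28S. It does not address what goes with depth, such as lanes or duplicate reads. A steeper version of a common unevenness predicts that windows rich in reads in testis rise in sperm and poor ones fall. On 28S the direction in the main scaling followed the testis level in 62% of called windows even at the most favourable turning level. The lowest possible value was 60%, the share of the more common direction. In the main scaling this argues against a steeper common unevenness as the whole account on 28S. Other scalings, which changed the split by direction, were not tested in this way. The windows were also called with both testis libraries, so noise in the library that gave the level can lower the value. On 18S the value was 79.4%, with 64.7% the lowest possible, which leaves a steeper common unevenness open. Slopes of sperm total RNA on the testis libraries across windows were 1.69 and 1.64 on 18S and 1.13 and 0.999 on 28S. Between the testis libraries they were 0.832 and 1.03 on 18S and 1.07 and 0.889 on 28S. The labelled kind of RNA as the whole cause also stays open, since tissue and kind are confounded outside a single library. In that library the median difference in the direction of the call was 0.99 log2 units, where the upper bound simulated for a further testis library was 0.16. A difference between the tissues in how rRNA is broken or degraded, the biological account that the design names, may contribute and was not tested separately.

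The near-empty stretch of 28S at positions 3023 to 3526 was weighed against loss in sperm alone and against a cause common to all libraries. The stretch was not empty in sperm alone, since the higher testis share was 1.14% (95% Wilson interval 1.10 to 1.19) for 10% of the molecule. Because the stretch was chosen as nearly empty in all groups, this restates the choice and is no separate test of loss in sperm. A common cause, such as base composition or the alignment reference, stays open. Of the 359 positions of the stretch that were poorly covered in all 3 sperm total RNA libraries, 83.0% were so in both testis libraries. This does not decide, since the stretch was chosen as nearly empty in all groups and 67.1% of all its positions were so in both testis libraries. Among its other 145 positions 27.6% were, but neighbouring positions are not independent. No single cause was tested, for want of a sequence, and a smaller additional loss in sperm (0.555% ± 0.426 against 0.996% ± 0.210) is neither shown nor excluded. The overlap of the groups rests on sperm total replicate 3, with 1.05% (95% Wilson interval 1.04 to 1.05), against 0.349% (0.347 to 0.351) and 0.272% (0.270 to 0.274) in replicates 1 and 2. Without it the sperm mean is 0.310% ± 0.0543, below both testis libraries.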
